A study of Homo sapiens with 12 samples.

How the data were processed

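RNA-seq and miRNA-seq were measured in HEK293T cells treated with ERI2 siRNA or control siRNA, with 3 libraries per group and assay. Per the labels' protocols, cells received 50 nM siRNA, were transfected again 48 hours after the first transfection and were harvested 72 hours after the second. The same protocol text speaks of ERI-1 siRNAs and of a harvest for microarrays, and it gives one long-RNA kit for all samples, so the small RNA kit is not given in the sources used here. Per the submitters' processing notes, CASAVA 1.8.2, TopHat2 2.0.10, HTSeq 0.6.1p1 and genome build hg19 were used, with no role or order stated. The strand setting, the annotation release, the miRNA aligner and the miRNA name release are not given in the sources used here.

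The authors deposited one table of raw read counts per gene (55765 names) and one of raw read counts per mature miRNA name (2588 names), per the values whole numbers with different totals per library. Every column name matched one sample, and 0 columns were left without a sample. Without the strand setting, reads from a gene and an antisense partner may be counted together, and genes with near-identical copies may share reads. Of the gene names, 18843 were tested, and of the miRNA names 1316. RNA-seq libraries held from 29.1 to 38.3 and miRNA-seq libraries from 0.723 to 1.03 (in units of 1e+06 counts), of which at least 99.9% and 99.3% fell in tested names. The highest gene, RN7SK, took from 3.02% to 3.80% of RNA-seq counts. No coordinates are given because the reference tables used here are of another build than hg19, and GC content, gene length and mature miRNA sequences were not used here.

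Counts as deposited were filtered with filterByExpr, scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood, robust) in R 4.3.3, each assay alone, at a Benjamini-Hochberg adjusted p under 0.05. Gene lists fixed before the data were examined were tested with limma 3.58.1 (camera, preset correlation 0.01, log2 CPM with prior count 2; fry) where at least 5 mRNA or 3 miRNA members were tested. The design, the lists, the alternatives and the rule for named genes were chosen before the data were examined. That rule named ERI2, ERI1 and ERI3; the 12 largest rises and falls (10 for miRNA) among names past the test with a mean of at least 10 CPM (100 for miRNA) and non-overlapping groups; the 3 smallest p-values in each direction; up to 4 members per mRNA list and 3 per miRNA list by p; and the 5 most abundant miRNAs. Other members are named only where a count was 5 or fewer or a change went against the rest. CPM values use TMM-scaled library sizes unless total counts are named.

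The lists covered the ERI family, small RNA machinery, RNA decay, histones, interferon, NF-kB, p53, integrated stress, heat shock, cholesterol, G1/S, G2/M, ribosomal proteins, ribosome biogenesis, oxidative phosphorylation, mitochondrial transcripts, glycolysis and hypoxia, TGF-beta and matrix, autophagy and lysosome, and neuronal, keratinocyte, fibroblast and blood markers, with 19 miRNA lists.

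Alternatives were DESeq2 1.42.0, limma-voom, RLE size factors, total library size, the upper quartile, no count filter, a filter of at least 1 CPM (10 for miRNA) in 3 libraries, the replicate number as a block, leaving out each library, an absolute log2 fold change of at least 1, an adjusted p under 0.01, leaving out miR-10a-5p, an estimated correlation and fry. The size factors from names not called lower and the analysis of replicates 2 and 3 alone were added after the data were seen.

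The fit was tested on simulated data. For the RNA-seq comparison of 18843 genes, 60% of 200 genes changed 1.5-fold were recovered with 6 false calls, and 77% of those changed 2-fold with 11 false calls. For the miRNA comparison of 1316 names, 38% and 75.5% were recovered at these sizes, with 7 and 4 false calls. When the 329 most abundant names were lowered 5-fold, 100% were recovered, with 46 false calls and a median of 0.20 for unchanged names.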

Results

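HEK293T cells, a human embryonic kidney line that carries a viral large T antigen, were transfected with siRNA against ERI2 or with a control siRNA. ERI2 belongs to a small family of exonucleases with ERI1 and ERI3. Long RNA and microRNA (miRNA) were each sequenced from 3 libraries per group, 12 libraries in all. The comparison asks which transcripts and which miRNAs differ between ERI2 siRNA and control siRNA, and knockdown below names the ERI2 siRNA group. There was no second ERI2 siRNA group or rescue, so other effects of the siRNA cannot be told apart from loss of ERI2. The cell line label reads HEK293T, while the growth protocol names the parental line HEK293. RNA-seq libraries held 34.5, 38.3 and 30.1 (in units of 1e+06 counts) in the control group and 32, 32.6 and 29.1 in the ERI2 siRNA group. miRNA-seq libraries held 0.808, 0.766 and 0.723 in the control group and 1.03, 0.742 and 0.943 in the ERI2 siRNA group. The labels do not say that the replicates were separate cultures, so the p-values measure the spread between these libraries, which may be technical. Replicates of one group differed by more than counting noise in both assays, with a chi-square per degree of freedom of at least 5.07 in RNA-seq and 2.09 in miRNA-seq.

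ERI2 mRNA, the target of the siRNA, was lower in each of the 3 knockdown libraries. It fell by 0.70 on the log2 scale (SE 0.0762; edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.000683). Its level was 55.7 ± 2.20 CPM (counts per 1e+06 counts; SD, n = 3) in control cells and 34.3 ± 1.67 CPM in knockdown cells, 61.6% of the control level. The counts were 1912, 2155 and 1562 in control libraries against 1091, 1205 and 984 in knockdown libraries. The related nuclease ERI1, which trims the ends of histone mRNA and ribosomal RNA, measured 28.4 ± 1.49 against 24.1 ± 2.08 CPM (SD, n = 3; log2 fold change -0.23, adjusted p = 0.112 in edgeR's quasi-likelihood test) and did not pass. ERI3 measured 59.1 ± 6.32 against 56.7 ± 3.67 CPM and did not pass either. Adjusted over the list alone, 2 of these 3 genes, ERI2 and ERI1, were lower. ERI2 kept its call without any 1 library.

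**Figure D1:**
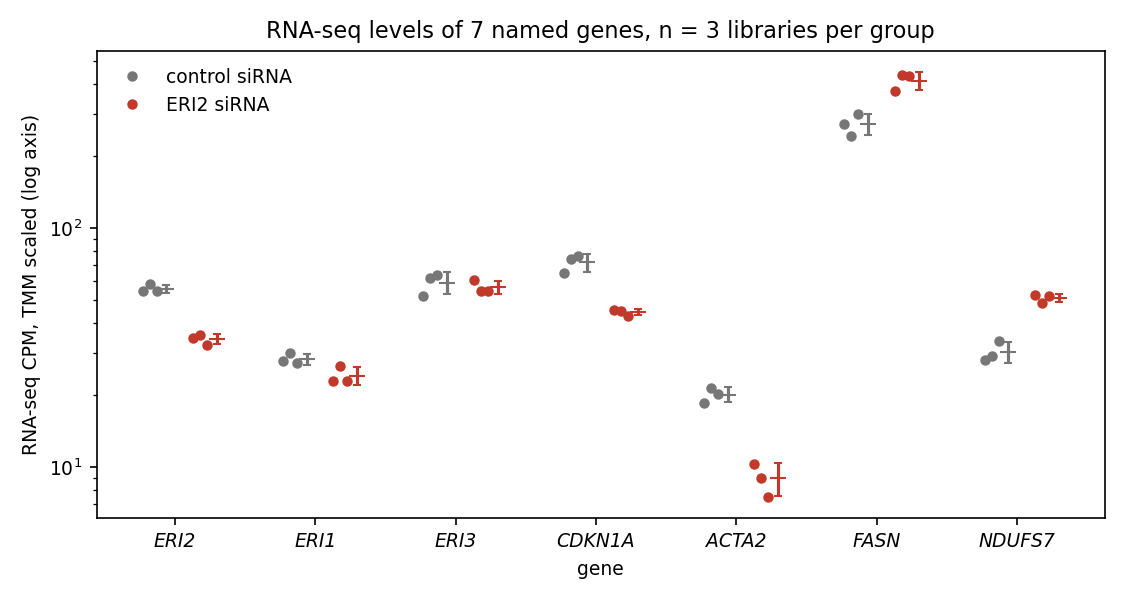
RNA-seq CPM (log axis) of 7 named genes in the 3 control and 3 ERI2 siRNA libraries; points are libraries, bars the mean ± SD. ERI2 lies at 55.7 ± 2.20 CPM in control and 34.3 ± 1.67 CPM in knockdown libraries, with no overlap.

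Across 18843 tested genes, 809 were higher and 800 lower after ERI2 knockdown, 8.54% of those tested. Most changes were small: the median absolute log2 fold change of the changed genes was 0.46, and 172 rose and 32 fell by at least 2-fold. A mean of at least 10 CPM was reached by 442 of the 809 higher and 663 of the 800 lower genes. Among rises at that level with non-overlapping groups, only MIR663B, MT-ND2 and a clone-named transcript reached 2-fold. The falls among genes of at least 10 CPM were led by ACTA2 (-1.16), a smooth muscle actin, GPRC5A (-0.91), a retinoic acid-induced receptor, LOX (-0.90), a collagen crosslinking enzyme, and JAG1 (-0.84), a Notch ligand. They were followed by SEPP1, TSPAN5, C14orf132 (each -0.79), SNORA53 (-0.78), ELOVL7, ALDOC, SCD5 (each -0.74) and SLC16A14 (-0.72). The rises were led by MIR663B (1.82), MT-ND2 (1.18), MRPL12 (0.93), a mitochondrial ribosomal protein, AP5Z1 (0.91), NEB (0.89) and CHTF18 (0.85). HIST3H2A (0.83), CAPN15 (0.80), NME1-NME2 (0.78), AC009404.2 (0.76) and TRABD (0.76) followed, and a clone-named transcript not named here rose by 1.13. The smallest p-values belonged to ANXA1 (-1.36), ACTA2 and SCD5 among falls and to MIR3648 (2.68), NDUFS7 (0.76) and MIR663B among rises (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p from 0.000632 to 0.00139). NME1-NME2 is a read-through gene and MT-ND2 has nuclear near-copies, so both values are uncertain.

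The groups did not overlap for 785 of the 809 higher and 797 of the 800 lower genes, and for 29.7% of all tested genes. The average over all groupings of the libraries is 10%. Genes share structure between libraries, so a single grouping can lie far from that average and the excess is no test of the knockdown. Under total library size, which moved the median of all genes from 0.003 to 0.06, the split was 976 higher to 463 lower, 67.8% higher against 50.3%. MT-ND2 and CHTF18 then no longer passed.

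Both replicate 1 libraries stood apart from replicates 2 and 3 of their groups, with no batch label to account for it. With replicates 2 and 3 alone, an analysis chosen after the values were seen, 2622 genes were higher and 2670 lower, including 779 of the 809 higher and 763 of the 800 lower genes. Of 5238 such genes tested in both fits, 56.4% had the same direction between control replicate 1 and knockdown replicate 1, with a median shift of 0.04 log2 units against 0.41 in replicates 2 and 3. Control replicate 1 lay with knockdown replicates 2 and 3 along a structure of the libraries that the labels do not name. Knockdown against control follows this structure in replicates 2 and 3 and runs against it in replicate 1. Values from either set alone, here and below, therefore cannot be told apart from it. ERI2 itself differed in replicate 1 as in the others, 54.4 against 34.6 CPM. The counts also depended on single libraries: 1221 higher and 1026 lower without control replicate 1, 299 and 425 without control replicate 2, and 271 and 214 without control replicate 3. They were 1424 and 1327 without knockdown replicate 1, 227 and 213 without knockdown replicate 2, and 176 and 195 without knockdown replicate 3.

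p53 target genes held more falls than rises. Of 29 tested, 12 fell and 1, SESN2, rose (19 and 1 adjusted over the list alone; 8 and 1 under total library size), with a median log2 fold change of -0.29. CDKN1A, an inhibitor of cyclin-dependent kinases, fell from 71.9 ± 6.20 to 44.5 ± 1.34 CPM (SD, n = 3), and CCNG1, which encodes cyclin G1, from 287 ± 34.1 to 180 ± 19.1 CPM. TP53INP1 (-0.68) and the death receptor gene FAS (-0.62) fell too, and the named members had adjusted p from 0.000928 to 0.0112 in edgeR's quasi-likelihood test. The list passed limma's camera test with a preset correlation (adjusted p = 3.64e-07), with adjusted p = 0.395 with an estimated correlation, and limma's fry test gave 0.0198. The median difference was -0.18 in replicate 1 and -0.30 in replicates 2 and 3.

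Of 32 genes of glycolysis and the hypoxia response 9 fell and none rose (13 lower and 1 higher adjusted over the list alone, 8 and 1 under total library size; 1 rise at an unadjusted p under 0.05, 0 rises by DESeq2 and limma-voom). ALDOC, an aldolase, fell from 16.9 ± 0.480 to 10.1 ± 2.03 CPM (SD, n = 3), and the mitophagy receptor BNIP3L (-0.51), the glucose transporter SLC2A3 (-0.49) and the enolase ENO2 (-0.39) fell as well. The camera test gave adjusted p = 0.000126, with adjusted p = 0.662 with an estimated correlation. The median difference of the list was -0.04 in replicate 1 and -0.31 in replicates 2 and 3.

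Of 40 genes of the extracellular matrix and TGF-beta targets, 12 were lower and 3 higher (15 and 3 adjusted over the list alone; 8 and 3 under total library size). ACTA2 fell from 20.1 ± 1.45 to 8.96 ± 1.40 CPM, LOX from 13.3 ± 0.888 to 7.14 ± 0.485 CPM and FN1, fibronectin, from 161 ± 12.9 to 116 ± 4.91 CPM (SD, n = 3). LTBP1, a latent TGF-beta binding protein, fell by 0.37. The 3 that rose, named after their values were seen, were ID1 (0.81), SMAD7 (0.41) and SMAD6 (0.47), of which both SMADs inhibit this pathway. The camera test gave adjusted p = 0.000246, with adjusted p = 0.567 with an estimated correlation. The median difference of the list was -0.38 in replicate 1 and -0.13 in replicates 2 and 3. Among markers of fibroblasts COL3A1 (-1.05, 5.92 to 2.85 CPM) and FBN1 (-0.35, 61.9 to 48.5 CPM) fell, 2 of 9 tested (5 adjusted over the list alone; 2 under total library size), while LGALS1 (-0.50, adjusted p = 0.111 in edgeR's test) and PDGFRA (-0.48, adjusted p = 0.111 in edgeR's test) did not pass. Of the 9 fibroblast markers 3 also stand in the matrix list and 1 reached 10 CPM; camera gave adjusted p = 0.0365, with adjusted p = 0.662 with an estimated correlation. The median difference of the fibroblast list was -0.32 in replicate 1 and -0.30 in replicates 2 and 3. The list no longer passed camera without control replicate 1 (adjusted p = 0.0832), control replicate 3 (0.104) or knockdown replicate 1 (0.0586), nor with replicates 2 and 3 alone (0.188).

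Interferon response genes were lower in 6 of 33 cases and higher in none (8 lower and 1 higher adjusted over the list alone, 4 and 0 under total library size; 5 rises at an unadjusted p under 0.05, 0 rises by DESeq2 and limma-voom). TRIM22 fell from 1.15 ± 0.0684 to 0.285 ± 0.0671 CPM, the RNA sensor IFIH1 from 4.43 ± 0.372 to 2.24 ± 0.122 CPM and SAMD9 from 11.7 ± 0.427 to 7.18 ± 0.204 CPM (SD, n = 3), and DTX3L fell by 0.42. Of the list's members, 12 reached 10 CPM. The camera test gave adjusted p = 0.000401, with adjusted p = 0.395 with an estimated correlation, and fry gave 0.00648; the median difference was -0.16 in replicate 1 and -0.36 in replicates 2 and 3. Of 9 markers of keratinocytes and cervical carcinoma lines 4 were lower (4 adjusted over the list alone): ANXA1 fell from 11 to 4.27 CPM, CAV1 from 16.9 to 10.7 CPM, CDH1 from 6.69 to 4.63 CPM and EPCAM from 1.54 to 0.749 CPM. Of these markers 2 reached 10 CPM and none stood in another list; camera gave adjusted p = 0.000848, with adjusted p = 0.395 with an estimated correlation, and fry gave 0.0198. The median difference of these markers was -0.20 in replicate 1 and -0.56 in replicates 2 and 3, and EPCAM and CDH1 no longer passed under total library size. Of the 6 blood cell markers tested, none passed edgeR's test (1 at an unadjusted p under 0.05, lower; 0 by DESeq2 and limma-voom; 0 adjusted over the list alone), none reached 10 CPM, and TAL1 (-0.66), LCP1 (-0.46) and CD14 (0.59) were among those with the smallest p-values; camera gave adjusted p = 0.378, with adjusted p = 0.761 with an estimated correlation.

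**Figure D2:**
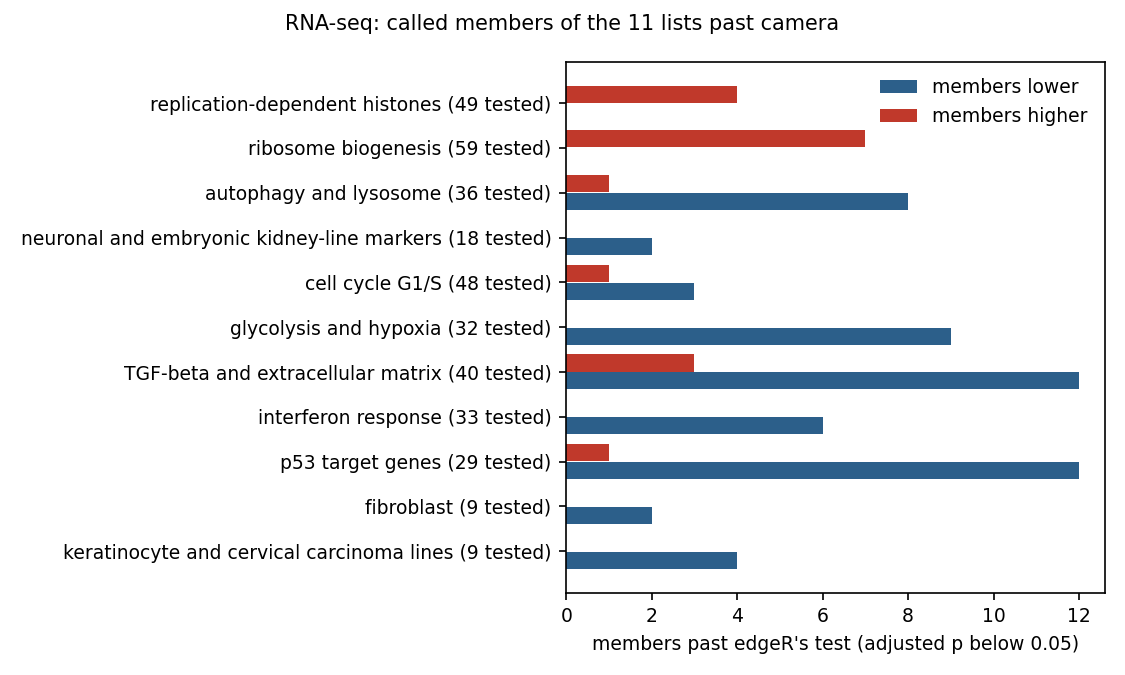
Number of members past edgeR's test (horizontal axis) in the 11 gene lists that passed limma's camera test with a preset correlation; blue bars are members lower and red bars members higher after ERI2 knockdown. The p53 list shows 12 lower and 1 higher of 29 tested, and ribosome biogenesis 7 higher of 59; none of the 11 lists passed with an estimated correlation.

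Among autophagy and lysosome genes 8 of 36 were lower and 1, the protease gene CTSD (0.32), was higher (10 and 3 adjusted over the list alone; 7 and 2 under total library size). WIPI1 (-0.50), the protease gene CTSB (-0.36) and the lysosomal membrane gene LAMP2 (-0.31) were among those that fell, LAMP2 from 204 ± 4.11 to 164 ± 5.60 CPM (SD, n = 3). Genes of the G1/S transition held 3 falls, RB1 (-0.42), the retinoblastoma gene, TYMS (-0.33), thymidylate synthase, and GINS1 (-0.29), and 1 rise, UHRF1 (0.30), of 48 tested (5 and 2 adjusted over the list alone; 2 and 2 under total library size). Of 18 neuronal and embryonic kidney markers, which HEK293 lines express in part, the neurofilament genes NEFL (-0.50) and INA (-0.49) fell (3 adjusted over the list alone; 2 under total library size), while NEFM (-0.44, adjusted p = 0.053 in edgeR's test) and TUBB3 (-0.37, adjusted p = 0.083 in edgeR's test) did not pass. Camera gave adjusted p of 0.0213, 0.0159 and 0.0470 for these 3 lists in the order named, with adjusted p of 0.712, 0.761 and 0.662 with an estimated correlation. Their median differences were -0.08, 0.06 and -0.02 in replicate 1 and -0.15, -0.18 and -0.19 in replicates 2 and 3, so the G1/S list turned sign between them. The lysosome list no longer passed without control replicate 3 (adjusted p = 0.0640 in camera). The G1/S list no longer passed without control replicate 2 (0.0867), control replicate 3 (0.0812) or knockdown replicate 3 (0.0704). The neuronal list no longer passed without control replicate 2, control replicate 3 or any knockdown replicate, with adjusted p from 0.0524 to 0.167 in camera.

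Some ribosome biogenesis and histone genes were higher. Of 59 ribosome biogenesis genes 7 rose (8 adjusted over the list alone; 13 under total library size), among them RRS1 (0.58), MYBBP1A (0.38), RRP12 (0.37) and the snoRNP protein gene NOP58 (0.36), which went from 136 ± 7.59 to 175 ± 15 CPM (SD, n = 3). Of 49 replication-dependent histone genes 4 rose (5 adjusted over the list alone; 12 under total library size): HIST2H2AA3 (1.11), HIST3H2A (0.83), HIST3H2BB (0.49) and HIST1H4J (0.48), the last from 61.2 ± 9.94 to 85.2 ± 12 CPM (SD, n = 3). Neither list held a fall in edgeR's test (0 and 1 at an unadjusted p under 0.05, 0 and 0 by DESeq2, 0 and 0 by limma-voom). Camera gave adjusted p of 0.00144 and 0.00199, with adjusted p of 0.761 for both with an estimated correlation. Both list results rested on replicate 1: the median difference was 0.33 and 0.60 log2 units there but -0.01 and -0.04 in replicates 2 and 3, where both lists turned Down and did not pass (adjusted p of 0.802 and 0.449 in camera). They also ended without control replicate 1 (adjusted p of 0.343 and 0.414 in camera) and without knockdown replicate 1 (0.207 and 0.303). HIST2H2AA3 may share reads with a near-identical copy. Of the 11 lists past camera, the 8 other than the p53, interferon and keratinocyte lists did not pass fry, with adjusted p from 0.109 to 0.491.

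Genes of the small RNA machinery changed in 2 of 30 cases (3 adjusted over the list alone; 4 under total library size, all higher). TNRC6A, a scaffold of the miRNA silencing complex, rose from 127 ± 2.18 to 161 ± 1.54 CPM, and TARBP2, a partner of Dicer, from 34.3 ± 1.74 to 41.2 ± 1.36 CPM (SD, n = 3). DGCR8, the partner of Drosha (0.29, adjusted p = 0.0522), and the exonuclease gene XRN1 (-0.16, adjusted p = 0.151) did not pass edgeR's test. Of 44 RNA decay genes EXOSC1 (0.28) rose and CNOT6L (-0.30) fell (4 and 1 adjusted over the list alone; 10 and 0 under total library size, where CNOT6L did not pass), while UPF3A (0.33) and EXOSC5 (0.32) did not pass.

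Of 39 genes of the integrated stress and unfolded protein response, 5 rose and none fell (5 adjusted over the list alone, 8 under total library size; 6 falls at an unadjusted p under 0.05, 3 falls by DESeq2 and 0 by limma-voom). They were SLC3A2 (0.49) and SLC7A5 (0.43), which form an amino acid transporter, the cystine transporter SLC7A11 (0.28), CHAC1 (0.57) and, named after its value was seen, SESN2 (0.24), which the p53 list also holds. FASN, fatty acid synthase, rose from 273 ± 28.4 to 415 ± 35.9 CPM (SD, n = 3) and MVD (0.44) rose in the cholesterol and lipid synthesis list, where STARD4 (-0.40) and FADS2 (-0.25) fell, of 32 tested (3 higher and 4 lower adjusted over the list alone; 2 and 1 under total library size). The median of that list was -0.03 and its mean 0.003, and camera gave the direction Down. HSF1 (0.34), a heat shock regulator, rose alone among 22 heat shock genes (1 adjusted over the list alone; 3 under total library size), while CHORDC1 (0.27), HSPA1B (0.23) and HSPA4L (-0.17) did not pass. Of the 5 lists from small RNA machinery to heat shock none passed camera, with adjusted p from 0.210 to 0.564 and, with an estimated correlation, adjusted p from 0.712 to 0.873. The heat shock list passed without control replicate 2 (adjusted p = 0.0349 in camera), but its median turned sign, from 0.36 in replicate 1 to -0.10 in replicates 2 and 3.

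NDUFS7, a complex I subunit, rose from 30.2 ± 2.99 to 51.1 ± 2.07 CPM (SD, n = 3) and ATP5D (0.39) rose, 2 of 78 nuclear genes of oxidative phosphorylation (2 adjusted over the list alone; 6 under total library size), while UQCR11 (0.31) and COX7A2 (-0.29) did not pass. Of 15 mitochondrially encoded transcripts 4 rose, MT-ND5 (0.56), MT-ND1 (0.49), MT-ATP8 (0.95) and MT-ND2 (1.18); adjusted over the list alone 4 were higher and 1 lower. Under total library size MT-ND5, MT-ATP8 and MT-ND2 no longer passed. No member passed edgeR's test among 79 ribosomal protein genes (1 higher and 4 lower at an unadjusted p under 0.05, 1 and 3 by DESeq2, 0 by limma-voom), 47 G2/M genes (1 and 4 unadjusted, 1 lower by DESeq2, 0 by limma-voom) or 17 NF-kB genes (1 lower unadjusted, 0 by DESeq2 and limma-voom), nor adjusted over the list alone; under total library size 1, 1 and 0 were higher. The smallest p-values among them were those of RPL41 (-0.26), RPLP1 (0.28), RPL37A (-0.23) and RPS19 (-0.21), of the mitotic genes HMMR (-0.34), KIF11 (-0.25), NUSAP1 (-0.18) and MAD2L1 (-0.21), and of CSF1 (-0.49), RELB (0.48), BIRC3 (-0.68) and NFKBIA (-0.12). The NF-kB list had a median of -0.02 and a mean of 0.000303. None of these 5 lists passed camera, with adjusted p from 0.118 to 0.899, and with adjusted p from 0.873 to 0.950 with an estimated correlation. The ribosomal protein, G2/M and oxidative phosphorylation lists passed camera as lower without control replicate 1 (adjusted p of 0.000147, 0.0266 and 0.000430) and without knockdown replicate 1 (0.000178, 0.00688 and 0.00123). In replicates 2 and 3 alone the ribosomal protein, G2/M and oxidative phosphorylation lists passed as lower (adjusted p of 6.84e-10, 0.000172 and 9.09e-07 in camera), with medians of -0.24, -0.13 and -0.21 there but 0.27, 0.21 and 0.19 in replicate 1. An effect of the knockdown on these lists cannot be told apart from the unnamed structure of the libraries.

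In the miRNA libraries the abundant families took a much smaller share of the counts after ERI2 knockdown. miR-10a-5p, the most abundant name, held 247794 ± 6177 CPM of total counts in control and 102178 ± 16885 CPM in knockdown libraries (SD, n = 3). miR-10b-5p went from 133427 ± 5314 to 45250 ± 6722 CPM, and miR-92a-3p from 67027 ± 1663 to 44132 ± 4540 CPM. Of 1316 tested miRNA names, 146 were higher and 303 lower by edgeR's quasi-likelihood test with TMM scaling, and 21 rose and 245 fell by at least 2-fold. The groups did not overlap for 444 of the changed names, and for 47.5% of all tested names. The average over all groupings of the libraries is 10%, from which a single grouping can lie far because names share structure between libraries.

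The higher and lower split depended on the scaling. TMM factors ran from 0.639 to 0.677 in control and from 1.45 to 1.63 in knockdown libraries, and the median log2 fold change of all names was 0.05 under TMM, 0.51 under the upper quartile and 1.27 under total library size. The split was 146 to 303 (32.5% higher) under TMM, 580 to 240 (70.7%) under the upper quartile and 1031 to 179 (85.2%) under total library size. With size factors from the 1013 names that TMM did not call lower, an alternative chosen after the values were seen, it was 41 to 346 (10.6%). The number of higher names was 84 without control replicate 1 and 74 without control replicate 3, against 146 in all libraries. Values below are under TMM unless total library size is named, and no spike-in counts that would set an absolute scale were used here.

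let-7 and miR-98, tumour-suppressive miRNAs, were lower in 10 of 13 names (10 adjusted over the list alone), with a median log2 fold change of -2.31 under TMM and -1.09 under total library size, where 10 were lower and 3 higher. let-7e-5p went from 922 ± 35.9 to 323 ± 55.2 CPM of total counts (SD, n = 3), let-7c-5p from 483 ± 34.6 to 168 ± 21.5 CPM and let-7g-5p from 1226 ± 47.5 to 573 ± 67.9 CPM. The family of miR-10, miR-99, miR-100 and miR-125, in part encoded in HOX clusters, was lower in 11 of 12 names (11 adjusted over the list alone; 9 lower and 1 higher under total library size), with a median of -2.51. miR-99a-5p (-3.01), miR-99b-5p (-2.82), miR-10b-5p (-2.77) and miR-125a-5p (-2.73) fell, with adjusted p from 9.49e-09 to 2.38e-08 in edgeR's quasi-likelihood test. miR-196a-5p (-2.75), miR-196b-5p (-2.15) and miR-615-3p (-1.88), also from HOX clusters, fell, 3 of 5 names (3 adjusted over the list alone; 3 lower and 2 higher under total library size).

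The miR-17~92 and related clusters, which promote cell cycle entry, were lower in 13 of 15 names (14 adjusted over the list alone; 11 lower and 1 higher under total library size), among them miR-19b-3p (-2.48), miR-25-3p (-2.28) and miR-93-5p (-2.23). All 11 names of the miR-30 family fell (11 adjusted over the list alone; 9 under total library size), with miR-30a-5p at -2.56, miR-30b-5p at -2.46 and miR-30a-3p at -2.36. The miR-15 and miR-16 family fell in 8 of 9 names (8 adjusted over the list alone; 5 lower and 1 higher under total library size), with miR-16-5p at 17798 ± 275 against 7766 ± 1296 CPM of total counts (SD, n = 3), miR-15b-5p at -2.65 and miR-15a-5p at -2.37. The miR-181 family had 7 names lower and 1, miR-181d-3p (0.36), higher, named after its value was seen (7 and 1 adjusted over the list alone, 7 and 1 under total library size); miR-181d-5p (-2.46), miR-181a-3p (-2.34) and miR-181b-5p (-2.12) fell. All 5 names of the miR-130 and miR-301 family fell (5 adjusted over the list alone; 4 under total library size), miR-301a-3p (-2.64), miR-301b-3p (-2.39) and miR-130b-3p (-2.26) among them. Also lower were 4 of 5 names of miR-34 and miR-449, of which p53 induces miR-34 (4 adjusted over the list alone). Under total library size 3 of these names were lower and 1 higher. The falls included miR-34a-5p (-2.67), miR-34c-5p (-2.30) and miR-449a (-2.61). All 3 names of miR-221 and miR-222 fell (3 adjusted over the list alone and 3 under total library size): miR-221-3p (-2.60), miR-222-3p (-2.28) and miR-222-5p (-1.65). In the group of miR-23, miR-24 and miR-27, 6 of 7 fell (6 adjusted over the list alone; 5 lower and 2 higher under total library size), with miR-23a-3p (-2.84), miR-27b-3p (-2.58) and miR-27a-3p (-2.51). Camera gave these 11 families adjusted p from 8.71e-07 to 0.0247, with adjusted p from 0.181 to 0.233 with an estimated correlation, and fry gave from 0.000246 to 0.00118, all Down. The miR-29 family, with miR-29b-3p (-2.46), miR-29a-3p (-2.31) and miR-29c-3p (-2.18) lower of 6 (3 adjusted over the list alone; 3 lower and 3 higher under total library size), did not pass camera (adjusted p = 0.0608, and adjusted p = 0.248 with an estimated correlation) but passed fry (adjusted p = 0.00118, Down). It passed camera without control replicate 1 (adjusted p = 0.0371), without knockdown replicate 3 (0.0305) and under total library size (0.0271).

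**Figure D3:**
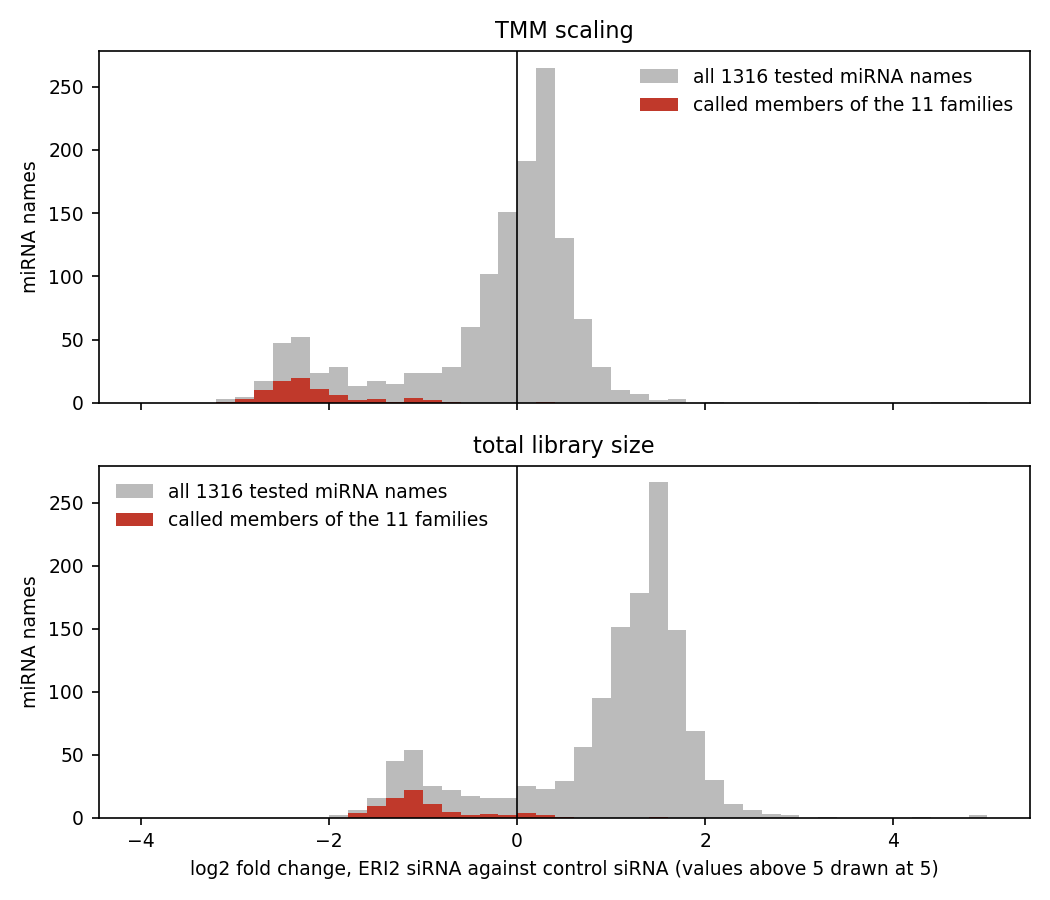
Number of miRNA names by log2 fold change of ERI2 siRNA against control siRNA, under TMM scaling (top) and total library size (bottom); grey bars are all 1316 tested names and red bars the members of the 11 families past edgeR's test under TMM. Most of these members lie below 0 in both panels, while the median of all names moves from 0.05 to 1.27.

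Outside the families, the falls of names of at least 100 CPM included miR-450a-5p (-2.74) and miR-186-5p (-2.67), and the smallest p-values also included the hypoxia-induced miR-210-3p (-2.37; 444 ± 20.7 to 201 ± 18.2 CPM of total counts, SD, n = 3). Rises were smaller under TMM: miR-7113-3p (0.89), miR-7158-3p (0.83), miR-411-3p (0.82), miR-6499-5p (0.80), miR-128-2-5p, miR-6894-5p and miR-1199-3p (each 0.78), miR-661 (0.74), miR-6857-5p and miR-887-3p (each 0.69) led the names of at least 100 CPM (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p from 3.33e-05 to 0.00301). Under total library size the order turned, with miR-7113-3p at 2.11, miR-7158-3p at 2.05 and miR-6499-5p at 2.03 against miR-450a-5p at -1.53, miR-186-5p at -1.45 and miR-210-3p at -1.14. Of the 5 most abundant names, miR-718 and miR-4465 did not pass under TMM (log2 fold changes 0.01 and -0.14), while under total library size both were higher, by 1.25 and 1.08. The smallest p-values among rises were those of miR-3976, with 5 counts over the control group and 314 over the knockdown group, miR-1468-3p, with 13 and 319, and miR-3686, with 0 and 169. Against a floor of 3 counts over the control group, miR-3686 was at least 47.7-fold higher relative to total counts; the floor covers counting error only.

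The imprinted DLK1-DIO3 cluster had 3 of 34 names higher and 1 lower (3 and 1 adjusted over the list alone). miR-323a-5p (0.56), miR-411-3p (0.82) and, named after its value was seen, miR-127-5p (0.62) rose and miR-127-3p fell by 0.57, although miR-127-3p was higher by 0.67 under total library size, where 34 of 34 names were higher. Camera gave adjusted p = 0.0247 for the cluster, with adjusted p = 0.181 with an estimated correlation, and it ended without control replicate 2 (adjusted p = 0.0732). Of 21 names made without Drosha or Dicer, 4 rose and 5 fell (4 and 5 adjusted over the list alone). miR-320a (-1.96), miR-484 (-1.36) and miR-320b (-1.14) fell, but under total library size miR-484 did not pass and miR-320b lay at 0.07. The median of this list was 0.20 and its mean -0.13, with camera Up (adjusted p = 0.569, and adjusted p = 0.567 with an estimated correlation) and fry Down (adjusted p = 0.00735). The chromosome 19 cluster gave 0 of 4 names and the stem cell miR-302 and miR-371 group 0 of 2 in edgeR's test (0 at an unadjusted p under 0.05, 0 by DESeq2 and limma-voom, 0 adjusted over the list alone), with miR-519d-3p (0.80), miR-1323 (0.29), miR-498 (0.18), miR-371b-5p (0.88) and miR-371a-3p (0.57). Under total library size all 6 were higher. Camera gave the chromosome 19 cluster adjusted p = 0.412, with adjusted p = 0.567 with an estimated correlation, and was not run on the group of 2.

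Marker miRNAs of other cell types did not pass camera as lists, but some passed fry as lower. Of 12 names from muscle, liver, brain and mesenchyme 6 fell and 2 rose (6 and 2 adjusted over the list alone; 5 lower and 7 higher under total library size), with miR-21-5p (-2.53; 716 ± 28.8 to 287 ± 36.2 CPM of total counts, SD, n = 3), miR-9-5p (-2.31) and miR-128-3p (-2.23) lower. Of 4 blood names miR-486-5p (-2.50; 2515 ± 204 to 1030 ± 122 CPM of total counts, SD, n = 3) and miR-486-3p (-1.58) fell (2 adjusted over the list alone; 1 lower and 2 higher under total library size) and miR-150-3p (0.13) did not pass. Of 6 epithelial names miR-141-3p (-1.02) fell (1 adjusted over the list alone), but lay at 0.19 under total library size, where 5 of the 6 were higher, and miR-203a-3p (0.87) and miR-205-5p (0.35) did not pass. Camera gave these 3 lists adjusted p of 0.0565, 0.215 and 0.433, with adjusted p of 0.252, 0.293 and 0.501 with an estimated correlation, while fry gave 0.000352 (Down), 0.000465 (Down) and 0.248 (Up). The list of muscle, liver, brain and mesenchyme names passed without control replicate 1 (adjusted p = 0.0371), without knockdown replicate 1 (0.0473) and under total library size (0.0345).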

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

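The tests on replicates 2 and 3 alone and with size factors from names not called lower were chosen only after the result was seen. ERI2 kept its direction and passed in each alternative except the minimum absolute log2 fold change of 1, which its value of -0.70 does not reach. Higher RNA-seq genes numbered 809 with all libraries, 1290 without a count filter, 172 with that minimum and 139 at an adjusted p under 0.01. Lower genes numbered 800 with all libraries, 463 under total library size, 32 with that minimum and 145 at an adjusted p under 0.01. Leaving out 1 library gave from 176 to 1424 higher and from 195 to 1327 lower genes, and replicates 2 and 3 alone gave 2622 and 2670. What made these counts vary stays open, and explanations for the replicate 1 difference are weighed below. With the replicate number as a block, 105 were higher and 98 lower, but the numbers did not pair the libraries: correlations of same-numbered libraries were -0.30, -0.08 and -0.10 in RNA-seq and -0.14, -0.06 and 0.00 in miRNA-seq, and 0 of the 6 control libraries correlated best with its own number. Of the 80 named RNA-seq genes past the test, 36 no longer passed without knockdown replicate 3, 27 without knockdown replicate 2, 26 without control replicate 3, 20 without control replicate 2, 6 without control replicate 1 and 5 without knockdown replicate 1; of the 66 named miRNAs at most 1, miR-141-3p, did not pass when 1 library was left out.

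mRNA lists past camera numbered 11 with all libraries, 0 with an estimated correlation, 3 by fry and from 7 to 11 when 1 library was left out. In replicates 2 and 3 alone the histone and ribosome biogenesis lists turned Down (adjusted p of 0.449 and 0.802 in camera). miRNA lists past camera numbered 12 with all libraries and 0 with an estimated correlation. The list of miRNAs made without Drosha or Dicer turned Down by limma's fry (adjusted p = 0.00735). Higher miRNA names numbered 146 with all libraries, 1031 under total library size, 580 under the upper quartile, 223 without a count filter, 21 with the minimum fold change, 58 at an adjusted p under 0.01, 41 with the added size factors and from 74 to 146 when 1 library was left out. Lower names numbered 303, and 179 under total library size. Under total library size miR-127-3p (0.67), miR-141-3p (0.19), miR-320b (0.0686) and miR-4465 (1.08) changed sign, as did miR-4465 (0.32) under the upper quartile; these settings move the centre of all names. At the depth of the miRNA libraries, 0.723 to 1.03 in units of 1e+06 counts, 38% of simulated 1.5-fold changes were recovered, so small changes could be missed.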

Other observations

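The tests on other splits of the libraries, on host genes and on target genes were set before their results were seen, although CDKN1A, COL3A1 and a few other target genes had been seen; every other test in this part was chosen only after the result was seen.

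Some genes for taste receptors, nearly all of the bitter type, were higher in RNA-seq. Of 71 groups of at least 20 genes that share a name prefix, the TAS group, TAS2R genes with TAS1R3 and some pseudogenes, had the smallest p in limma's camera (adjusted p = 1.99e-08), with adjusted p = 0.869 with an estimated correlation. Of 20 tested, 7 rose and none fell by edgeR's test, all 20 had a positive log2 fold change, and the median was 0.60 (0.65 under total library size, 0.63 under the upper quartile). TAS2R13 (0.84), TAS2R18 (0.78), TAS2R31 (0.66) and TAS2R30 (0.62) rose from levels of 3.28 to 11.5 CPM, and near-identical receptor genes can share reads. Of 73 small nucleolar RNA genes of the H/ACA class (SNORA), 9 were lower, among them SNORA53 (273 to 159 CPM), SNORA22 (235 to 161 CPM) and SNORA12 (58.7 to 41.3 CPM), and 1, SNORA73 (1.07), was higher. Camera gave this group adjusted p = 0.0150, with adjusted p = 0.869 with an estimated correlation, and SNORA31, SNORA79, SNORA35, SNORA33 and SNORA73 no longer passed under total library size. The Cajal body RNA genes SCARNA1 (-0.53), SCARNA10 (-0.50), SCARNA21 (-0.45) and SCARNA13 (-0.27) fell and SCARNA2 (0.40) rose, of 21 tested; SCARNA13 no longer passed under total library size. Pseudogenes of the signal recognition particle RNA and related RN genes held 10 rises in 138, of which RN7SL751P (0.51) reached 7.18 CPM and RN7SL648P (0.91) 5.34 CPM. The abundant RN7SL3 fell by 0.58 from 2077 to 1391 CPM. These copies may share reads, which leaves their values uncertain. Of 120 MIR genes 10 rose and 2, MIR3609 (-0.38) and MIR210HG (-0.46), fell, neither of which passed under total library size. Among the rises MIR663B reached 16.1 CPM and MIR3648 12.1 CPM in knockdown libraries, and the others only 0.484 to 2.83 CPM. Camera passed 14 of the 71 prefixes and none with an estimated correlation (adjusted p = 0.869 for each of the groups named here). The TAS median was 0.26 in replicate 1 and 0.81 in replicates 2 and 3, the RN median 0.05 and 0.71, the MIR median -0.03 and 0.55, the SNORA median -0.35 and -0.06, and the SCARNA median -0.35 and -0.16.

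Among miRNAs, the fall was more frequent in names with low numbers. Of names numbered 1 to 50, 63 of 74 (85.1%) were lower, of names from 201 to 500 50 of 115 (43.5%), and of names above 5000 22 of 359 (6.13%). The 99 tested members of 12 families, the 11 past camera and miR-29, took 56.4 ± 0.705% of counts in control and 24.2 ± 3.52% in knockdown libraries, while names numbered from 1000 on took 22.3 ± 0.696% and 55.7 ± 3.35% (SD, n = 3; two-sided exact permutation p = 0.1 for each, the smallest that 3 against 3 libraries allow). Of 31 hairpins of these families with both arms tested, taken whatever their change, the less abundant arm fell less in 24. Its median was -1.40 against -2.37 for the more abundant arm (two-sided permutation p = 0.00137, 100000 resamples). That permutation flipped signs over hairpins as if they were independent, so its p-value does not measure the spread between libraries. Of the 8 hairpins whose less abundant arm reached 100 CPM, this arm fell less in 5, with medians of -2.31 against -2.41. miR-3686, miR-3976 and miR-1468-3p stood apart with 169, 314 and 319 knockdown counts against 0, 5 and 13, while the other arm miR-1468-5p had 11 against 8 counts; no explanation was tested for them.

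Other splits of the libraries bear on how far chance can be excluded. The 10 splits of 6 libraries include the real one, which the following counts hold too. For changed RNA-seq genes 1 split, the real one, reached 1609 (highest other 0). For changed miRNAs 1 split, again the real one, reached 146 higher and 303 lower (highest other 0). For the lists, 5 splits reached 11 mRNA lists past camera (highest other 11) and 1, the real one, 12 miRNA lists (highest other 7). With 10 splits the share cannot fall under 0.05.

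The lower miRNA families and the small rises of other names form one pattern, for which scaling, dilution and a loss of miRNA, through host genes or through active miRNA, were weighed. TMM scaling alone is argued against for falls in the share of counts: 72 of the 84 lower members of these 12 families (85.7%) were also lower under total library size. Both scales are relative, so this cannot decide on composition or on absolute levels. Scaling stays open for the rises, of which 41 of 146 (28.1%) remained with size factors from names not called lower. Over members of at least 100 CPM, of which miR-29 has none and miR-34 with miR-449 has 1, the medians of 11 families lay within 0.738 log2 units of each other (-2.75 to -2.01), but 3 of these 56 members, let-7d-3p (0.16), miR-181d-3p (0.36) and miR-615-5p (-0.12), did not fall, and less abundant arms below that level fell less, so 1 common dilution by fragments counted under other names and a shared loss of mature miRNA, which predict the same medians, both stay open. Less transcription is argued against for the host genes tested, by a median log2 fold change of -0.023 over 24 hosts (95% bootstrap interval -0.105 to 0.0443). These values are amounts of host RNA, so transcription of the miRNA precursors themselves was not measured. The hosts carry lower miRNAs inside and outside the families. The bootstrap treats them as independent, although some, such as CTDSPL and CTDSP2, were listed for the same miRNA. Of the 24 hosts 1, CTDSP2 (-0.36), was lower and 1, R3HDM1 (0.34), higher. No host was tested for let-7, miR-10 with miR-99, miR-100 and miR-125, miR-181, miR-221 with miR-222, miR-29, or miR-34 with miR-449. The same holds for miR-196, whose list had only HOXC5, the host of miR-615. In other families, such as miR-30 and miR-130 with miR-301, the hosts covered only part of the members. Less transcription stays open for these families and for all members without a tested host. Textbook targets lay at a median of -0.0462 relative to all genes (interval -0.0777 to 0.0283, 59 genes), and the list did not pass limma's camera. The interval lies under the bound of 0.1 set beforehand against a loss that frees targets, and that rule alone would argue against such a loss. This is not taken as deciding, because 3 members rose (TRIM71, NR6A1, EZH2) and 7 fell, the bootstrap treats genes as independent and the bound was an assumed size. These reasons were not part of the rule set beforehand.

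The second pattern lies around replicate 1 of RNA-seq: the split of control replicate 1 with knockdown replicates 2 and 3 against the other 3 libraries had 4050 genes at an unadjusted p under 0.05, against 4999 in the real split and from 117 to 673 in the other 8, although 0 passed edgeR's adjusted test, which points to a structure of the samples. Knockdown against control in replicates 2 and 3 alone coincides with this split, so results there cannot be told apart from it. The comparison of all libraries is also unbalanced over it. Of 5238 genes called from replicates 2 and 3 alone, 56.4% had the same direction in replicate 1, which shares no library with them. A weaker knockdown in knockdown replicate 1 is argued against by ERI2, which lay 0.0205 log2 units above the mean of the other knockdown libraries, and a swap with control replicate 1 by ERI2, 0.653 log2 units higher in control replicate 1. An earlier form of the swap test used that share of 56.4%, which lay between its bounds. A batch that crosses the groups stays open and may lie behind the structure, since the labels give none to test. Library measures separated the same sets. TMM factors were 1.02, 1.03 and 1.04 in control replicate 1 and knockdown replicates 2 and 3, against 0.954 to 0.987 in the other libraries. Gene names with counts above 0 numbered 26817, 27150 and 26995 against 25841 to 26333.

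The third pattern is a pair of small RNA genes in control replicate 1. SNORD3A measured 93.9 CPM there against 2647 and 5182 CPM in the other control libraries, and RNU4-2 77.9 against 1449 and 1973 CPM. Single low genes were not confined to that library: 3 genes lay more than 3 log2 units under the median of the other libraries in control replicate 1, 4 in control replicate 2, 1 in control replicate 3 and 1 in knockdown replicate 1. A loss of such RNAs as a class is argued against by a median of 0.18 log2 units over 181 other small nucleolar and spliceosomal genes (middle range 0.00394 to 0.375) in control replicate 1 relative to the other controls. What set these genes apart stays open, and no biological explanation was tested.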
